A study of Homo sapiens with 2 samples.

How the data were processed

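SMCHD1 occupancy was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in SH-SY5Y, an established human neuroblastoma cell line. Per the labels, chromatin was fixed with 1% formaldehyde, sheared by sonication and precipitated with an antiserum against SMCHD1. There were 2 samples, 1 from untreated cells and 1 from cells given 5-azacytidine (5azaC), an inhibitor of DNA methyltransferases, at 8 µM for 72 h with a new dose every 24 h. Each sample is described as a pool of 20 replicates, so each condition was 1 pooled library, and no spread between replicates could be measured.

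Peaks were called with MACS2 on GRCh37 (hg19), per the submitters' processing notes. The version, the aligner, the control library and the read depth are not given in the sources used here. Each deposited file is a list of 2100 peaks with chromosome, start, end and a peak name, and carries no score, fold or p-value column. The name ends in a running number. These numbers rise with position on every chromosome, and the chromosomes follow one another in alphabetical order of their names. A number missing between neighbouring peaks of 1 chromosome was therefore counted as a call that is not listed here. Calls before the first or after the last listed peak of a chromosome cannot be counted this way. In the 5azaC list no number was missing within any of the 23 chromosomes, whereas 2918 were missing in the untreated list. All listed peaks lay on chromosomes 1 to 22 and X. The order of rows within a chromosome did not follow position (median absolute Spearman correlation 0.125 in the untreated list). It ran in parallel between the lists for peaks that paired 1 to 1 (median Spearman correlation 0.90 over 23 chromosomes, across peaks, which are not independent replicates), and it was used as an ordering of strength in 1 alternative.

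Peaks were compared by overlap of at least 1 bp (bedtools 2.31.1, python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1). Observed counts were set against 1000 random placements of the peaks within their own chromosome. Placements left out the centromere gap and any peak-free stretch of over 5 Mb that adjoined it or opened a chromosome. Percentiles among placements describe these 2 lists. Shares are given with 95% exact (Clopper-Pearson) binomial intervals, which cover counting error only and treat peaks as independent. Two-sided Fisher's exact tests with Benjamini-Hochberg adjustment, over 23 chromosomes or over 16 locus lists, compare the 2 lists and not the conditions, because each condition was 1 library and the lists have many peaks in common. Widths of shared and unshared peaks of 1 list were compared with a two-sided permutation test of 100000 resamples.

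Chromosome lengths, centromere gaps and 91 locus windows on GRCh37 were entered from general knowledge of that build after the lists had been read, because the gene table used here belongs to another build, from which no coordinate was taken. No peak lay past a chromosome end or inside a centromere gap, and 20 of 23 chromosomes had a peak within 100 kb of the gap in each list. Of the windows, 83 had a symbol in the gene table. All 83 were on the same chromosome there, and all 61 pairs of neighbouring windows kept their order. Window edges are approximate. The gene lists were fixed before the data were examined, and 87 windows over 15 lists stand for them. Another 4 windows, of repeat arrays and of a nuclear insertion of mitochondrial DNA, were chosen after the peak positions had been seen. A peak was counted at a locus if it lay within 10 kb of the window. Values of 2 single loci are not reported here, and their peaks are part of the list counts.

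The peaks named in the text are the 8 widest of each class (shared, only untreated, only 5azaC), the 3 windows of 1 Mb with the most peaks, and loci with peaks, up to 4 per list by number of peaks. Width took the place of a score. This rule, with width as its fallback, the tests, the gene lists, the gained chromosome arms and the first set of alternatives were fixed before the data were examined. The test foreseen for scores was run on widths. Naming genes with 3 or more peaks was not possible without gene positions on this build. Naming the nearest gene of each peak, the share of peaks in promoters, exons and introns, and the GC and CpG content of peaks need an annotation and a sequence of GRCh37 and were not analysed here. The alternatives were a reciprocal overlap of 0.5, a distance of 1 kb, the first 0.5 of each chromosome's rows as a stricter list, lists of the widest peaks, merging of peaks within 1 kb, other distances and other placements. Counts based on all running numbers, a local placement and a centromere gap joined with its adjoining peak-free stretch were added after the data had been seen. Densities of arms away from centromeres use the joined gap. On simulated lists of 2100 peaks, all 700 planted shared peaks were recovered, and running numbers of a thinned list gave back 97.9% of the calls.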

Results

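The data were 2 lists of SMCHD1 peaks, 1 from untreated SH-SY5Y neuroblastoma cells and 1 from cells treated with 5azaC. SMCHD1 is a non-canonical SMC protein known for silencing on the inactive X chromosome, at clustered autosomal genes and at the D4Z4 repeat. The comparison addressed where SMCHD1 sits in the genome and how this differs when DNA methylation is lowered with 5azaC. Each condition was 1 pooled library, so a difference between the lists has no replicate check. The read depth is unknown, and all coordinates are on GRCh37.

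Each list held 2100 peaks, but the untreated list was part of a longer numbered set. Running numbers in the peak names spanned 5018 calls on the 23 chromosomes in untreated cells and 2100 after 5azaC, 2.39 times as many without treatment. The untreated list thus held 41.8% of its numbered calls, and the 5azaC list held all of those between its first and last peak of each chromosome. Another 350 numbers of the 5azaC list and 522 of the untreated list fell between the last peak of chromosome 9 and the first of chromosome X and could not be placed. How the listed untreated peaks were selected is not given in the sources used here. If they are the strongest calls, listed widths, shares and locus counts compare a selected part of the untreated calls with a 5azaC list that was not thinned within chromosomes. Listed peaks were wider in untreated cells, with a median of 310 bp (quartiles 236 and 471 bp) against 251 bp (199 and 362 bp). The same order held at matched places, although pairing does not remove the selection of listed untreated peaks. Among 1433 peaks that paired 1 to 1, 1236 were narrower after 5azaC and 181 were wider, and the median ratio of widths was 0.888. With 1 library per condition and unknown read depth, this does not show that 5azaC narrows peaks.

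**Figure D1:**
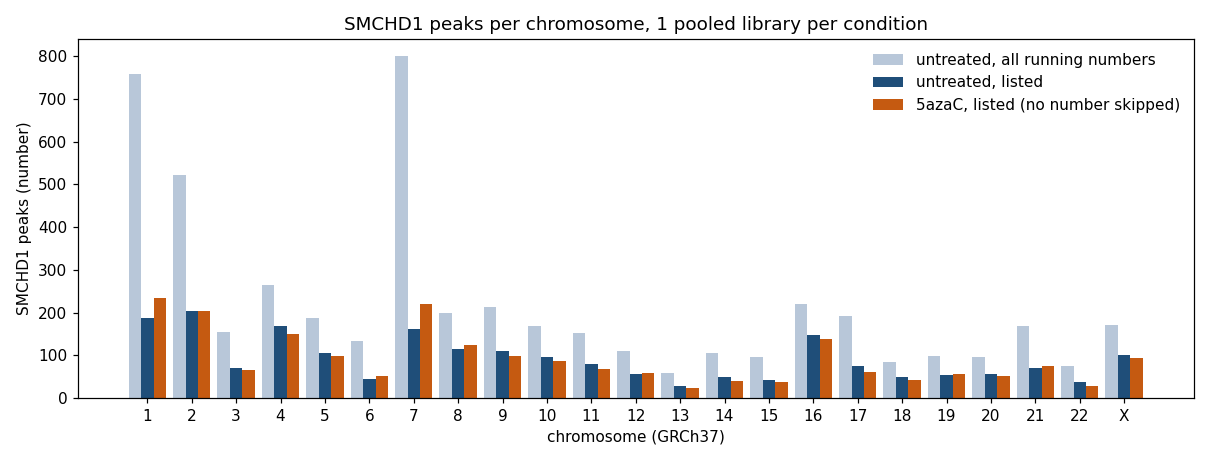
Number of SMCHD1 peaks (y axis) on each chromosome (x axis) in 1 pooled library per condition: all running numbers of the untreated list (light bars), its listed peaks (dark blue) and the 5azaC peaks (orange). Chromosome 7 had 801 numbered calls in untreated cells, of which 162 were listed, and 221 after 5azaC.

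Most listed peaks were called at the same place in both conditions. Of the listed untreated peaks, 1472 overlapped a 5azaC peak (70.1%, 95% interval 68.1 to 72.0%), and 1504 of the 5azaC peaks overlapped a listed untreated peak (71.6%, 69.6 to 73.5%). The untreated share does not carry over to all untreated calls. Of those, 2918 were unlisted, and only 596 5azaC peaks lacked a listed untreated partner. Random placement of the 5azaC peaks gave 1.36 ± 1.17 shared untreated peaks (SD over 1000 placements, highest 7). Moving each 5azaC peak by its own random distance of 10 to 100 kb gave 52.4 ± 6.78 (highest 75). Such moves keep the regional density of peaks but not their spacing within small clusters. Neither comparison can tell recurring SMCHD1 binding from recurring read pile-ups, because no control library was available. Peaks found in both lists were wider than the others, by 103.5 bp in the median for untreated cells (348.5 against 245 bp) and by 78 bp after 5azaC (281 against 203 bp). Both differences had p = 1e-05 in the permutation test over peaks, the smallest it can give. On 18 of the 23 chromosomes the peak in the first row of the untreated list overlapped the peak in the first row of the 5azaC list.

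Of the 8 widest shared peaks, 6 lay within 2.09 Mb of a centromere gap, and the other 2 were on chromosome 1. A peak of 4151 bp was the first listed on the long arm of chromosome 1 (142535508 to 142539658). It lay 18 Mb past the centromere gap with no listed peak between. The joined gap, which takes in this peak-free stretch, ends at the peak, so by that measure the peak is next to the gap. At this peak, 5azaC peaks covered 2870 bp. A peak of 3225 bp on chromosome 6 (58776262 to 58779486) lay 0.0507 Mb from the centromere gap and matched 3230 bp after 5azaC. Chromosome 4 held 2 of the 8 widest, at 49120389 to 49123307 (2919 bp) and 49098774 to 49101253 (2480 bp), both next to the centromere. Others were on chromosome 10 (38815750 to 38818773, 3024 bp), chromosome 7 (56438223 to 56440736, 2514 bp) and chromosome 16 (33238807 to 33241255, 2449 bp). The second peak on chromosome 1 (2583494 to 2586603, 3110 bp) was 2.58 Mb from the short-arm end.

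Peaks found in 1 list were narrower. The 628 untreated peaks without a 5azaC partner had no 5azaC call at their place, since that list skips no number within or between chromosomes other than from 9 to X. This is open for at most 1 of them that lay before the first 5azaC peak of chromosome X. It is also open for any past the last 5azaC peak of chromosome X, which were not counted. The widest were at 158133928 to 158135024 on chromosome 7 (1097 bp), 1.00 Mb from the long-arm end, at 17517787 to 17518777 on chromosome 5 (991 bp) and at 42712035 to 42712904 on chromosome 10 (870 bp). The other 5 of the 8 widest lay on chromosomes 22, 7, 21 (2 peaks) and 4, and measured 776 to 855 bp. The peak on chromosome 4 (190767359 to 190768134) was 0.386 Mb from the long-arm end. The reverse class could be resolved only in part. Of 596 5azaC peaks without a listed untreated partner, 62 lay between untreated peaks with consecutive numbers, where no untreated call was made. At 520 at least 1 untreated number was skipped, and 14 lay beyond the first or last listed untreated peak. The widest of the 596 were 794 bp (86803981 to 86804774) in the REXO1L array on chromosome 8 and 585 bp (47217513 to 47218097) on chromosome 21, both with skipped untreated numbers. The other 6 of the 8 widest measured 496 to 562 bp and also lay where untreated numbers were skipped, so none of the 8 can be called specific to 5azaC.

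Listed peaks were concentrated next to centromeres in both conditions. In untreated cells 801 peaks (38.1%, 36.1 to 40.3%) lay within 2 Mb of a centromere gap, against 2.97% under random placement, a 12.8-fold excess. After 5azaC there were 734 (35%, 32.9 to 37.0%) against 2.92%, a 12-fold excess. The densest windows of 1 Mb were the same in both lists. The window from 49 to 50 Mb on chromosome 4 held 70 untreated and 67 5azaC peaks, 42 to 43 Mb on chromosome 10 held 49 and 44, and 61 to 62 Mb on chromosome X held 43 and 39. The listed shares near centromeres did not differ past the threshold (Fisher's exact test, adjusted p = 0.0689 over 2 classes). Counted over all running numbers, calls near centromeres numbered 1176 to 1280 in untreated cells and 734 after 5azaC, a ratio of 1.60 to 1.74. Elsewhere they numbered 3738 to 3842 and 1366, a ratio of 2.74 to 2.81, as 104 skipped numbers could lie in either place. Near centromeres thus lay 23.4 to 25.5% of the untreated numbered calls and 35% of the 5azaC calls, the reverse order of the listed shares. Of the untreated peaks near centromeres, 73.4% (70.2 to 76.4%) overlapped a 5azaC peak, against 68.1% (65.4 to 70.6%) of those farther away. For 5azaC peaks the shares were 81.6% (78.6 to 84.3%) and 66.3% (63.7 to 68.8%), set against an untreated list that leaves out more of its calls away from centromeres than near them.

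**Figure D2:**
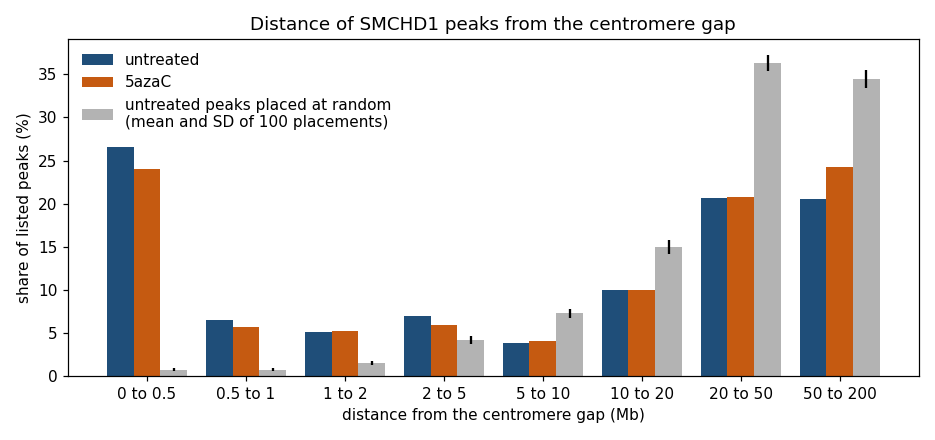
Share of listed SMCHD1 peaks (y axis, %) by distance from the centromere gap (x axis, Mb) in untreated cells (blue), after 5azaC (orange) and for untreated peaks placed at random (grey, mean and SD of 100 placements). Within 0.5 Mb lay 26.6% of untreated and 24% of 5azaC peaks, against 0.730% of placed peaks.

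Chromosome ends were also overrepresented, with similar shares of listed peaks in both lists. Within 2 Mb of an end lay 208 untreated peaks (9.90%, 8.66 to 11.3%) and 210 5azaC peaks (10.0%, 8.75 to 11.4%), 3.16 and 3.30 times the random share. The listed shares there did not differ past the threshold (Fisher's exact test, adjusted p = 0.959), which does not show that they are equal. Shares near ends over all running numbers were not computed. Of 46 chromosome ends, 18 had an untreated peak within 100 kb and 20 had a 5azaC peak, and 18 ends had both. The 46 include the short-arm ends of chromosomes 13, 14, 15, 21 and 22, which lie in peak-free stretches left out of the placements.

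At the loci of the gene lists, most peaks lay in a few clusters: the FRG1 to DUX4 window, FRG2B, the GAGE cluster and the 5S ribosomal RNA cluster. The window from FRG1 to DUX4 at 4q35, which holds the D4Z4 repeat linked to facioscapulohumeral muscular dystrophy, had 8 untreated peaks (190841365 to 191044236 on chromosome 4) and 4 5azaC peaks (190881020 to 191044249). The related subtelomere around FRG2B at 10q26 had 6 and 5. Together the 4q35 and D4Z4 list held 14 untreated and 9 5azaC peaks, against 0.505 and 0.464 under random placement. The 5S ribosomal RNA cluster at 1q42 had 9 untreated peaks (228744648 to 228781987 on chromosome 1) and 8 5azaC peaks, and the tRNA cluster at 1q23 had 1 and 2. The GAGE cluster of cancer-testis genes, which are silenced by DNA methylation in most somatic cells, had 8 untreated peaks (49161843 to 49360839 on chromosome X) and 10 5azaC peaks. Up to 15 unlisted untreated calls could lie at GAGE and up to 41 at the 5S cluster, whereas the 5azaC list skipped no number there. No listed peak was found at the CT47A, CT45A, MAGEA or SPANX clusters. These 3 lists exceeded each of the 1000 placements in both conditions. In the stricter part of each list by row order only 1 list did, and the FRG1 to DUX4 window, FRG2B and GAGE were left with 1 peak each in both conditions. The placements do not keep the clustering of peaks, so several neighbouring peaks in 1 cluster can exceed them. Read pile-ups on repeated copies were not tested at these loci.

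The clustered protocadherins, cell adhesion genes known as SMCHD1 targets in mouse and human cells, had no listed peak in either condition, nor did the 4 HOX clusters. Of 12 imprinted loci only IGF2R had a peak, shared between the conditions (160521752 to 160522057 on chromosome 6 in untreated cells). H19 and IGF2, KCNQ1 and CDKN1C, the stretch from MKRN3 to UBE3A, and GNAS had none. Random placement gave 0.440 untreated peaks at the protocadherin clusters, 0.553 at the HOX clusters and 2.63 at the imprinted loci, so these absences lay within the range of the placements. For 5azaC the absence holds for all calls between the first and last peak of each chromosome. For untreated cells it holds for listed peaks, since unlisted calls could lie at 61 of the 70 loci of the gene lists that were empty in both peak lists.

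Neuroblastoma identity genes were also free of listed peaks in both lists. None was found at the 11 adrenergic loci, among them HAND2, GATA3 and MYCN, transcription factors of sympathetic neurons and neuroblastoma, or at the 6 mesenchymal loci, among them VIM, FN1 and PRRX1. Random placement gave 0.990 and 0.393 untreated peaks there, so these absences were within chance. Long genes of synapse and axon guidance held fewer peaks than random placement gave, with 4 untreated peaks against 24.9 (95% of placements 15 to 35) and 8 5azaC peaks against 26.4 (17 to 36). CSMD3 had 2 peaks in each condition, CNTNAP2 had 1 and 3, and MAGI2 had 0 and 2. Up to 57 unlisted untreated calls could lie at CNTNAP2 and up to 47 at MAGI2. The listed counts therefore do not show more calls at these genes after 5azaC. Protocadherins and cadherins outside the clusters (PCDH15, PCDH9, CDH12 and CDH13) had none, against 3.95 and 3.60 placed. Zinc finger clusters on chromosome 19 had 4 peaks in each list and olfactory receptor clusters had 4 in each, within the range of the placements. The chromatin regulators SMCHD1, DNMT1, DNMT3A, DNMT3B and EZH2 and the interferon response loci had no listed peak. Of the DNA damage loci only ATM had a peak, in untreated cells (108134221 to 108134470 on chromosome 11).

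Of the 16 locus lists, 7 had no peak in both conditions, and 5 had enough peaks for the test between the peak lists to pass the threshold. None of those 5 did (Fisher's exact test, lowest adjusted p = 1, with 0 lists at an unadjusted p under 0.05). Over the 87 loci of the gene lists there were 46 untreated and 46 5azaC peaks. The 4 windows chosen after their peaks had been seen held 46 untreated and 42 5azaC peaks. Among them were the REXO1L array at 8q21 (24 and 25), the RS447 array of USP17 genes at 4p16 (13 and 9) and the DXZ4 array at Xq23 (5 and 4). The last was the nuclear insertion of mitochondrial DNA at 1p36, which is not a repeat array (4 and 4, with each of the 4 shared). Without a control library, binding at these 4 windows cannot be told apart from read pile-ups.

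**Figure D3:**
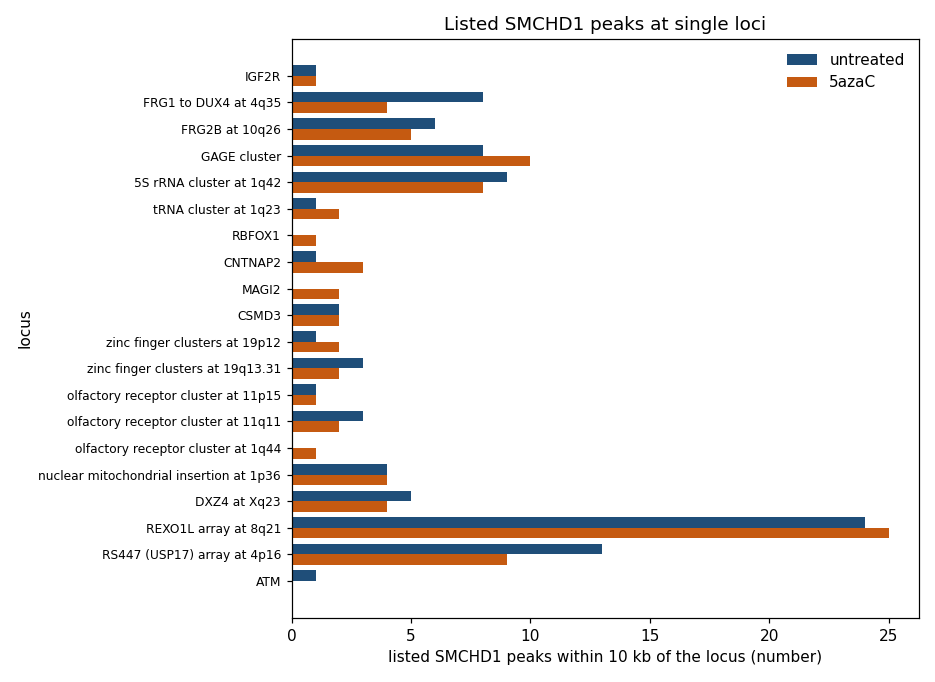
Number of listed SMCHD1 peaks (x axis) within 10 kb of 20 of the 21 loci (y axis) that had any, in untreated cells (blue) and after 5azaC (orange). The REXO1L array had the most, 24 and 25, and the window from FRG1 to DUX4 had 8 and 4.

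Chromosome 7 differed between the lists in opposite directions for listed peaks and for all numbered calls. Among listed peaks, chromosome 7 held 7.71% (6.61 to 8.94%) in untreated cells and 10.5% (9.24 to 11.9%) after 5azaC, and was the only chromosome to pass the threshold (Fisher's exact test, adjusted p = 0.0425). This call was lost with peaks merged within 1 kb (Fisher's exact test, adjusted p = 0.0627) and in the stricter list by row order (adjusted p = 0.643). Among numbered calls it held 16% in untreated cells against 10.5% after 5azaC (Fisher's exact test, adjusted p = 2.55e-08). The difference between the listed shares thus reverses when the unlisted calls are counted. Chromosome 1 also held more of the numbered calls in untreated cells (15.1% against 11.1%, Fisher's exact test, adjusted p = 9.04e-05). Chromosomes 4, 8 and 16 held less (5.26% against 7.14%, 3.95% against 5.86% and 4.38% against 6.52%, Fisher's exact test, adjusted p = 0.0123, 0.00318 and 0.00167). In listed peaks chromosome 1 (8.90% against 11.1%), chromosome 4 (8.00% against 7.14%) and chromosome 16 (7.05% against 6.52%) lay the other way, without passing the threshold, and chromosome 8 lay the same way (5.43% against 5.86%). The X chromosome, which makes up 5.34% of the placeable length, held 101 untreated peaks (4.81%, 3.93 to 5.81%) and 94 5azaC peaks (4.48%, 3.63 to 5.45%).

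Pooled, the 5 chromosome arms known to carry gains in SH-SY5Y had more peaks per Mb than the other autosomal arms. Over the whole arm, 17q did not in listed peaks. The 5 arms, named before the data were examined and counted whole, were 7p, 7q, 1q, 2p and 17q. Listed peaks were 1.62 times as dense there in untreated cells (95% interval 1.45 to 1.80) and 2.04 times as dense after 5azaC (1.85 to 2.26). On 17q there were 0.644 listed untreated peaks per Mb against 0.676 on the other arms, and 0.554 against 0.641 after 5azaC. Away from centromeres the order was the reverse, with 0.482 on 17q against 0.404 in untreated cells and 0.445 against 0.385 after 5azaC. The upper quartile of the other arms was exceeded by 2 of the 5 arms in untreated listed peaks and by 4 after 5azaC. Counted over all running numbers, the untreated ratio was 3.71 (3.50 to 3.93), with 4.70 calls per Mb on these arms and 1.27 on the others. Between the conditions, numbered calls fell from 1932 to 538 on these arms, a ratio of 3.59, and from 2904 to 1468 on the other autosomal arms, a ratio of 1.98.

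**Figure D4:**
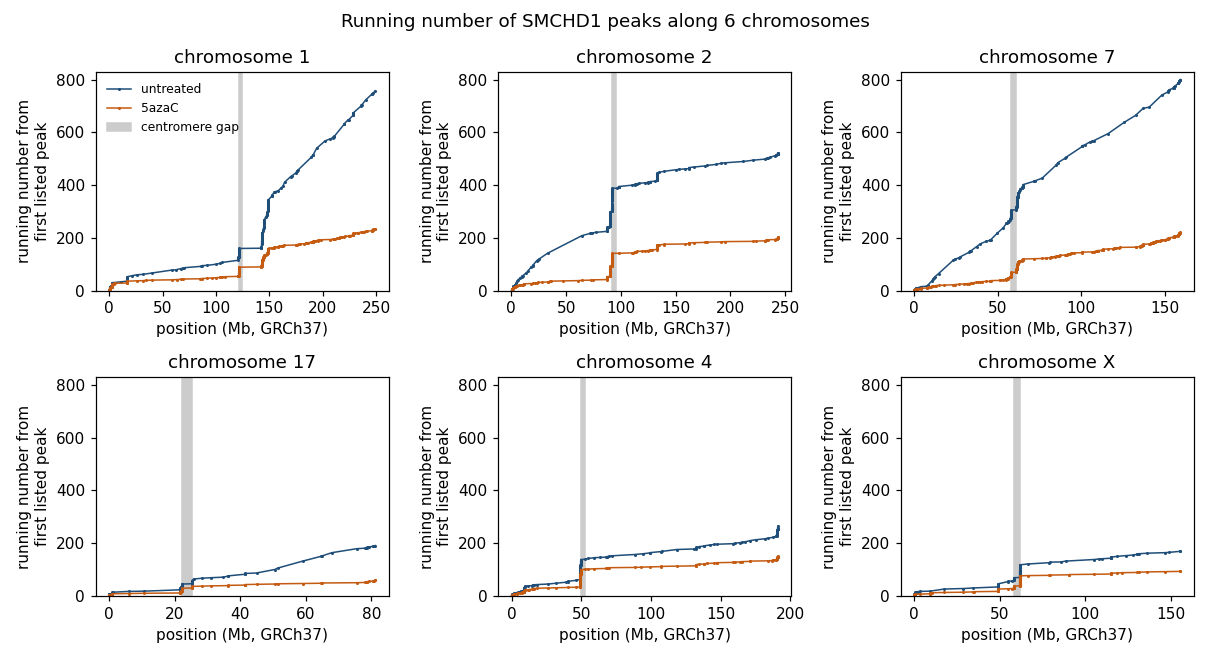
Running number of SMCHD1 peaks counted from the first listed peak (y axis) against position (x axis, Mb) on chromosomes 1, 2, 7, 17, 4 and X in untreated cells (blue) and after 5azaC (orange), with 1 point per listed peak and the centromere gap in grey. The untreated numbers reach 758 on chromosome 1 and 801 on chromosome 7, against 264 on chromosome 4 and 170 on chromosome X.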

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

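The tests in this part were chosen after the values had been seen, except that the gained arms had been named before.

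Running numbers were skipped between chromosomes as well as within them. Between the last peak of chromosome 9 and the first of chromosome X, 522 running numbers were skipped in the untreated list and 350 in the 5azaC list. In the 5azaC list no number was skipped between any other pair of neighbouring chromosomes, and in the untreated list the other pairs skipped 31 together. The ratio of the skipped numbers was 1.49. Where these calls lie was not analysed here.

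The density of calls on 1q, 2p, 7 and 17q may reflect extra copies of this DNA in SH-SY5Y. Away from centromeres, all 5 arms exceeded the upper quartile of the other autosomal arms in untreated numbered calls (0.977 per Mb), with 4.98 on 1q, 4.58 on 7p, 4.37 on 7q, 2.86 on 2p and 2.32 on 17q, against 3 of 5 in untreated listed peaks and 4 of 5 after 5azaC, where 17q (0.445) was under the quartile (0.535). Pile-ups at centromeres are argued against as the whole cause, since at most 18.1% of the untreated calls on the 5 arms (16.4 to 19.9%) could lie there. The density ratio was 4.66 in untreated calls and 2.31 after 5azaC, so copies alone, with the same effect in both libraries, leave that difference unexplained. A higher true density of SMCHD1 on these arms stays open, because copy number was not measured here.

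The smaller number of calls after 5azaC may come from a shallower or weaker 5azaC library, or from loss of SMCHD1 under 5azaC, and these cannot be told apart. Calls of a shallower library would nearly all be among the untreated calls. Of the 5azaC calls, 2.95% (2.27 to 3.77%) lay where no untreated number was skipped and 28.4% had no listed untreated partner, so the share absent from untreated cells lies anywhere between, and read depth is unknown. Loss of the same share of calls all over the genome is argued against, because away from centromeres the ratio of untreated to 5azaC calls was 4.44 (3.96 to 5.00) on the gained arms and 2.20 (2.03 to 2.39) on the others. An even drop in signal is not excluded by this, since it can remove more calls where more of them lie near the threshold.

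The crowding of peaks near centromeres in both lists may come from reads of collapsed repeats piled up on the assembled copies, or from SMCHD1 bound to these repeats. Untreated peaks near centromeres were found after 5azaC more often than those elsewhere by 5.36 points, with overlapping intervals. Either explanation allows this, and without a control library they cannot be told apart.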

How the results depend on the processing

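No paired analysis was possible because each condition was 1 pooled library, which also left no replicate to leave out. Counts over all running numbers, peaks away from centromeres only, local placement and the joined centromere gap were chosen after seeing the data. The stricter list by row order left 1056 peaks in each list. It raised the shared share to 80.6% of untreated and 82.5% of 5azaC peaks, and the share near centromeres to 46.9 and 43.9%. It lowered the share near ends to 8.43% in both lists, the peaks at loci of the gene lists to 15 and 13, and the lists above each placement from 3 to 1 in both conditions. All numbered calls raised the untreated count to 5018 and the untreated density ratio of gained arms to 3.71, lowered the untreated share near centromeres to 23.4 to 25.5% and raised the number of chromosomes that differ from 1 to 5. They reversed chromosome 7, from 2.81 points higher after 5azaC to a difference of -5.44 points (Fisher's exact test, adjusted p = 2.55e-08). The reversal follows from the construction, since 639 of the 801 untreated calls there are unlisted. The call on chromosome 7 also ended with merged peaks (2.95 points, Fisher's exact test, adjusted p = 0.0627) and in the stricter list (2.84 points, adjusted p = 0.643), which left 0 chromosomes that differ, and the cause was not tested. Reciprocal overlap of 0.5 gave shared shares of 63.3% in both lists, a distance of 1 kb gave 73.7 and 73.9%, and peaks away from centromeres gave 68.1 and 66.3%. Moving peaks by 10 to 100 kb gave 2.49% shared by chance in place of 0.0647%. Shares near centromeres were 45.1 and 40.9% within 5 Mb, 34.1 and 31.7% with merged peaks and 42.9 and 40.2% with the joined gap. Shares near ends were 13.6 and 14.5% within 5 Mb. Away from the joined gap the 5azaC density ratio of gained arms was 2.31. The other 31 alternatives of the main results stayed within their interval, within 1.5 times the count or on the same side of the threshold, equal-sized lists of the widest peaks and whole-genome placement among them. For single loci 42 alternatives stayed and 15 moved, all in the stricter list except the olfactory receptor cluster at 11q11, which had 0 untreated peaks inside its window. Genomic location and sequence content were not run. Unknown depth limits each statement on calls lost or gained.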

Other observations

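The rise in running number was not even along 2p and 17q, in stretches chosen after the plot of running numbers had been seen. On 2p, untreated numbers rose by 3.25 per Mb between listed peaks at 0.307 and 64.6 Mb and by 1.05 per Mb from there to 76.9 Mb. On 17q they rose by 1.26 per Mb between 28.4 and 45.0 Mb and by 3 per Mb between 50.5 and 81.2 Mb. In the same intervals the 5azaC list held 38 and 3 peaks on 2p (0.591 and 0.243 per Mb) and 8 and 15 on 17q (0.480 and 0.489 per Mb).

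The DXZ4 array at Xq23, a macrosatellite known for its role in the folding of the inactive X chromosome, had untreated peaks between 115000465 and 115005247, of which 3 of 5 overlapped a 5azaC peak. In the RS447 array 9 of 13 untreated peaks had a 5azaC partner, and in the window from FRG1 to DUX4 4 of 8 did. Each of the 9 and 4 5azaC peaks there overlapped an untreated peak.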
